A study of Mus musculus with 5 samples.

How the data were processed

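Gene expression was measured with an Affymetrix mouse array in total RNA of ID8 cells, a mouse ovarian surface epithelial line that forms peritoneal tumours and ascites in mice. The labels give 3 arrays of cells grown in DMEM with 10% fetal bovine serum (FBS; replicates 1, 2 and 3). They give 2 arrays of cells grown with 10% ascites fluid from ID8-bearing mice (replicates 2 and 3). The series design gives 7 days for the ascites culture. Its wording does not settle whether the FBS culture lasted as long, or whether the ascites medium also held FBS. Nothing in the labels says that replicates came from separate cultures, so the p values of genes measure only the spread between these arrays, which may be technical.

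Per the labels' protocols, RNA was extracted with a spin-column kit after shredding of the lysate and labelled with biotin by the manufacturer's procedure. Per the submitters' processing notes, the arrays were processed with Affymetrix Expression Console. Its version and the summarisation algorithm are not given in the sources used here. The deposited values are on the log2 scale, as judged from their range, with 2 decimals and 1 value per probe set on each of the 5 arrays. The distributions of the deposited values nearly coincide, with medians of 7.4 to 7.47 and means of 7.524 to 7.529 per array, so they were used with no further normalization. If the submitters forced the distributions together, a change of total RNA per cell cannot be seen in them. The values carry no background or detection call, so the precision is limited by the number of arrays and, for dim genes, by an unknown background.

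Of 22690 probe sets, 64 were array controls. Probe sets were named from the platform annotation. It gave 1 gene for 20393 probe sets and several genes for 691, and 1555 others were not listed in it and stayed unnamed. Of the probe sets with 1 gene, 20364 were found through their Entrez identifier in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. That table was used for names only, and no coordinates are printed. Each of 12394 genes was represented by its probe set with the highest mean over all 5 arrays, and 4958 genes had more than 1 probe set. In 1 gene, Smim7, probe sets passed the threshold in opposite directions. No filter on dim genes was applied, and 112 genes had the same value on all 5 arrays.

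Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), with p values adjusted by the Benjamini-Hochberg method and a threshold of 0.05. The fit had 3 residual degrees of freedom, and eBayes added 1.33 prior degrees of freedom. The arrays were fitted together, and log2 changes are ascites minus FBS. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 32 lists that were fixed from textbook knowledge before the data were examined. Camera sets the members of a list against the other genes, which the preset takes as nearly independent. Its p values therefore rest mainly on the number of genes and the spread among them, and do not measure replication between arrays. Camera with an estimated correlation, and fry, which tests whether the genes of a list move on balance in one direction without comparing them with other genes, were the alternatives. Members of each list were counted as risen or fallen after adjustment over all genes and after adjustment over the list alone. A further 8 lists were chosen after the data had been seen, and are reported only in the closing observations. For Hspa5 an exact two-sided permutation test was added.

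Named genes followed a rule set before the data were examined. They were the 10 largest rises and 10 largest falls past the threshold with no overlap between the groups' arrays, Hspa5, and up to 4 members of each list with the largest change past the threshold, or the member with the smallest p where none passed. Other members of these lists are named where their values describe the list, and were chosen after their values were seen. Genes without an assigned name were to be skipped, which removed 0 genes.

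The calculation was tested on simulated data for ascites against FBS with 12394 genes. It recovered 71% of 100 genes changed by 1 on the log2 scale and 80% of 100 genes changed by 2, with 5 unchanged genes called. Camera with the preset correlation called a list that had been moved and 0 of 200 lists that had not. Noise was drawn independently for each gene and array, with the same spread on every array, whereas in the real data FBS replicate 3 stood apart from the other FBS arrays. The recovery and the number of false calls may therefore not hold for the real comparison. Nor does the simulation show how the preset correlation behaves for lists whose members vary together. Camera with an estimated correlation gave the moved list an adjusted p of 0.107, above the threshold, and fry gave 0.000289. The moved list was tested together with the 200 unmoved lists, whereas the real comparison was adjusted over 32 lists. The simulation therefore does not show whether camera with an estimated correlation would miss such a shift among 32 lists.

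Alternatives chosen before the data were examined were the replicate number as a block, quantile normalization, median centring, leaving out the lowest 25% or 50% of genes by mean level, the mean of all probe sets of a gene, an intensity trend in eBayes, array weights, leaving out each array in turn, a per-gene statistic without moderation, limma's treat against a 1.2-fold change, and an adjusted p below 0.01. After FBS replicates 1 and 2 were seen to differ far less from each other than from replicate 3, averaging them as 1 sample was added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.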

Results

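The study asked how culture in tumour ascites changes ovarian cancer cells, and in particular whether it favours stem-like cells that carry the chaperone GRP78, the product of Hspa5, at their surface. Expression of 12394 genes was compared between ID8 cells grown in 10% FBS (n = 3 arrays) and ID8 cells grown for 7 days in 10% ascites (n = 2 arrays). Gene values are log2 array signals, given as mean ± SD, and changes are ascites minus FBS with their standard error (SE). Adjusted p values are limma's for genes and camera's for gene lists. However small, the camera values with the preset correlation do not measure replication between arrays. The arrays measured total transcript levels, not protein at the membrane.

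The groups were separated along the first principal component, which held 69.4% of the variance. The FBS arrays did not lie together. FBS replicates 1 and 2 differed from each other by an SD of 0.117 over genes, and 0 genes differed at least 2-fold between them. FBS replicate 3 differed from each of them by an SD of 0.427, and it set the second component, with 23.2% of the variance. The ascites arrays differed by an SD of 0.239, and 39 genes differed at least 2-fold between them. FBS and ascites arrays differed by SDs of 0.508 to 0.6.

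**Figure D1:**
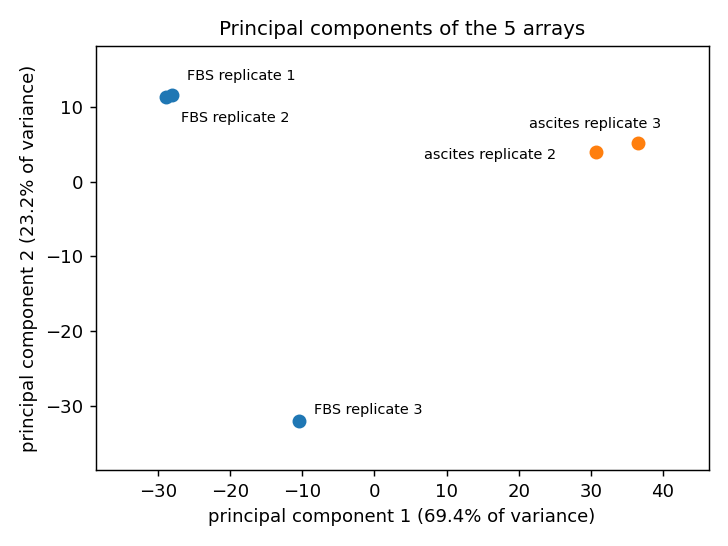
Principal components of the 5 arrays, with the first component (69.4% of the variance) on the horizontal axis and the second (23.2%) on the vertical axis; each point is an array, blue for FBS and orange for ascites. The ascites arrays sit at 30.7 and 36.5 on the first component and the FBS arrays at -28, -28.8 and -10.4, with FBS replicate 3 apart at -32.1 on the second.

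ID8 cells grown in ascites had lower transcript levels of cholesterol synthesis enzymes and of mitotic genes, and higher levels of ATF4 stress-response targets, NRF2 antioxidant targets and p53 targets, than cells grown in FBS. In all, 654 of 12394 genes changed, of which 333 rose and 321 fell, and 291 of them changed at least 2-fold (146 up and 145 down). Of the 32 gene lists, 12 shifted by camera with its preset correlation, 4 up and 8 down, and 0 did with an estimated correlation (lowest adjusted p = 0.175). At an unadjusted p below 0.05 there were 3006 genes, where 620 would be expected by chance. The groups' arrays did not overlap for 38% of all genes, where chance gives 20%, and for all 654 changed genes. These chance values, 620 genes and 20%, take the arrays as independent. FBS replicate 1 and FBS replicate 2 were nearly alike (SD of 0.117 over genes), so chance may give more. The size of the excess over chance therefore cannot be judged. Genes past the threshold would seldom overlap in any case, so the lack of overlap for the 654 is no added evidence.

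The number of genes past the threshold depended on which arrays were used. It fell to 0 without FBS replicate 1 (2088 genes at an unadjusted p below 0.05), without FBS replicate 2 (2017), without ascites replicate 2 (2748) and without ascites replicate 3 (2415), and to 0 with FBS replicates 1 and 2 averaged as 1 sample (2128), while it rose to 2494 without FBS replicate 3. Each gene called in the following paragraphs shares this limit. Without FBS replicate 3, the FBS spread rested on replicates 1 and 2 alone, which differed by an SD of only 0.117 and may be near-technical repeats. The larger counts and smaller p values given below without that array may therefore overstate the evidence.

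The largest rise in signal was in Bcl2l15, a BCL2 family member, from 4.79 ± 0.41 to 10.31 ± 0.32 (adjusted p = 0.0156). Gsta2, a glutathione S-transferase, rose 43.4-fold, from 6.18 ± 0.70 to 11.62 ± 0.08 (log2 change 5.44, SE 0.44, adjusted p = 0.0191). Close paralogs of this gene family may not be separated by a probe set. P2rx3, an ATP-gated ion channel, rose from 5.39 ± 0.30 to 10.00 ± 0.36 (adjusted p = 0.0156), and Car6, a secreted carbonic anhydrase, rose 20.9-fold (SE 0.52, adjusted p = 0.0309). Cth, cystathionine gamma-lyase, which makes cysteine, rose 19.4-fold, from 7.12 ± 0.39 to 11.39 ± 0.01 (adjusted p = 0.0158). Cyp3a13, a cytochrome P450, rose 18.3-fold (SE 0.11, adjusted p = 0.00588). Stbd1, a glycogen-binding protein, rose 12.6-fold, Glrp1 by 3.58 on the log2 scale, the glycosyltransferase gene B4galnt2 from 4.93 ± 0.18 to 8.31 ± 0.75 and the casein gene Csn3 9.74-fold. Another probe set moved by only 0.25 for B4galnt2 and by -0.02 for Csn3. The FBS signals of Bcl2l15, P2rx3 and B4galnt2 lay within or below the range of the median levels of the lists of other cell type markers (4.85 to 5.48), so they were not shown to lie above background and no fold is given. The rank of Bcl2l15 above Gsta2 therefore rests on a signal that may be background. Cyp3a13 in FBS (5.67) lay little above this range of medians, so its fold is uncertain too. The same holds for Gsta2, whose FBS arrays read 5.99, 5.59 and 6.95, and for Stbd1 (6.16 in FBS). Folds given further below with a similar lower signal, such as those of Fgf21 (6.04 in FBS) and Thbs1 (6.08 in ascites), share this limit.

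The largest falls were in Aqp5, a water channel, which was 14.9-fold lower in ascites (11.60 ± 0.42 against 7.70 ± 0.07, log2 change -3.90, SE 0.27, adjusted p = 0.0168), and in Plce1, a phospholipase C, which was 12.4-fold lower (log2 change -3.63, SE 0.56, adjusted p = 0.0454). The sterol genes Fdps, Idi1 and Stard4 were also among the 10 largest falls. The others were C1qtnf1, a secreted C1q-like protein, at 8.73-fold lower, Dpysl5 at 8.58-fold, the growth factor gene Fgf18 at 8.45-fold, the vesicle protein gene Sv2a at 7.93-fold and Mgp, a matrix protein, at 7.83-fold (adjusted p between 0.0144 and 0.0378). Dpysl5 (5.73), Mgp (5.99) and Sv2a (6.14) in ascites lay little above the range of those marker list medians, so their folds are uncertain.

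Cholesterol synthesis and SREBP2 targets fell as a list (camera adjusted p = 8.71e-15, median log2 change -2.02). All 19 measured members were lower in ascites, of which 13 fell after adjustment over all genes and 17 fell adjusted over the list alone. Fdps, farnesyl diphosphate synthase, was 10.1-fold lower (11.91 ± 0.29 in FBS against 8.58 ± 0.44 in ascites, adjusted p = 0.0191), although its other probe set did not move (0.00). Idi1, which isomerises the isoprenoid unit, was 8.82-fold lower (adjusted p = 0.0243) and Stard4, a sterol carrier, 8.50-fold lower (adjusted p = 0.0181). Srebf2, which encodes SREBP2 itself, was 6.08-fold lower (10.63 ± 0.06 against 8.03 ± 0.11, adjusted p = 0.0062). The list was higher in FBS replicate 3 than in replicates 1 and 2 by a median of 0.53, and 17 members fell when that array was left out. With an estimated correlation the adjusted p was 0.449, and with fry 0.00887.

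Fatty acid synthesis genes also fell as a list (camera adjusted p = 0.00887, adjusted p = 0.449 with an estimated correlation). Of 17 measured members, 4 fell and 0 rose, and adjusted over the list alone 8 fell and 2 rose. The members that fell were desaturases and an elongase. Fads2 was 6.31-fold lower (log2 change -2.66, SE 0.16, adjusted p = 0.0158), Scd2 3.12-fold, Fads1 2.54-fold and Elovl5 1.67-fold. The list's camera adjusted p was 0.14 without ascites replicate 2, and its median moved from -0.71 to -0.40, with 10 members fallen, without FBS replicate 3. Fry kept the call (0.00818). Fatty acid oxidation and PPAR targets shifted up (camera adjusted p = 0.0332, median 0.19), with 2 of 21 members risen and 6 adjusted over the list alone. These were Pdk4, which restrains pyruvate oxidation, at 3.23-fold (adjusted p = 0.0196), and Angptl4, a lipase inhibitor, at 2.16-fold (adjusted p = 0.0245). This call was lost without FBS replicate 3 (adjusted p = 0.169, median 0.08, 6 risen and 3 fallen), where the list was lower than in replicates 1 and 2 by a median of -0.29, without ascites replicate 2 (0.14), with array weights, with fry (0.128) and with an estimated correlation (adjusted p = 0.558).

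Mitotic cell cycle genes fell as a list (camera adjusted p = 6.23e-13, median log2 change -1.19). Each of the 24 measured members was lower in ascites, 10 fell after adjustment over all genes, and 21 fell adjusted over the list alone. The proliferation marker Mki67 was 3.56-fold lower (11.43 ± 0.28 against 9.60 ± 0.11, adjusted p = 0.0245). The mitotic cyclin gene Ccnb2 was 3.34-fold lower, the centromere histone gene Cenpa 3.23-fold and Birc5 (survivin) 2.90-fold. With an estimated correlation the adjusted p was 0.449, and with fry 0.0303. DNA replication and S phase genes were lower in 23 of 23 members and shifted down as a list (camera adjusted p = 3.8e-06, median -0.65), but 0 members passed the limma threshold over all genes, 10 had an unadjusted p below 0.05, and 6 fell adjusted over the list alone. E2f1, the member with the smallest p, changed by -0.65 (SE 0.12, adjusted p = 0.0653). This call was lost with an estimated correlation (adjusted p = 0.591) and with fry (0.195). FBS replicate 3 lay above replicates 1 and 2 by a median of 0.41 for the mitotic list and 0.67 for the DNA replication list. Without it 16 mitotic genes fell, and the DNA replication list had 11 members fallen and a smaller median of -0.37.

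The p53 targets and senescence list rose (camera adjusted p = 9.25e-07, median 0.96), with 9 of 18 members risen and 0 fallen, and 12 risen and 1 fallen adjusted over the list alone. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose 6.57-fold, from 10.62 ± 0.03 to 13.34 ± 0.06, at an adjusted p of 0.00312, which was the lowest of all genes and shared with St8sia1. Plk2 rose 2.62-fold, the nuclease gene Aen 2.57-fold and Zmat3 2.50-fold (adjusted p between 0.0383 and 0.0446). Mdm2, Fas, Bbc3, Ccng1 and Phlda3 also rose. The senescence-associated members Cdkn2a and Cdkn2b changed by 0.00 and -0.10 and did not pass. Leaving out FBS replicate 3 gave 11 risen and 2 fallen members. With an estimated correlation the adjusted p of the list was 0.175, and with fry 0.000838.

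ATF4 and CHOP targets, which respond to amino acid shortage and other stress, rose as a list (camera adjusted p = 6.76e-12, median 1.32). Of 22 measured members 21 were higher in ascites, 8 rose after adjustment over all genes, and 19 rose adjusted over the list alone. Besides Cth, the lipoprotein receptor gene Vldlr rose 5.33-fold (log2 change 2.41, SE 0.34, adjusted p = 0.0403), the cystine transporter gene Slc7a11 4.28-fold (2.10, SE 0.21, adjusted p = 0.0245) and Fgf21 2.80-fold (adjusted p = 0.0222). Other members that rose were Slc3a2, Mthfd2, Slc7a5 and Asns. Ddit3, which encodes CHOP, was 2.82-fold higher (SE 0.26, adjusted p = 0.0575) and Atf4 itself changed by 0.45, and neither passed. Another probe set of Vldlr moved by 0.33. Leaving out FBS replicate 3 gave 15 risen and 1 fallen. With an estimated correlation the adjusted p was 0.175, and with fry 0.0028.

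NRF2 and glutathione genes rose as a list (camera adjusted p = 1.81e-10, median 0.77), with all 22 measured members higher in ascites, 7 risen over all genes and 14 adjusted over the list alone. After Gsta2, the largest rises were in Gsta3 at 8.33-fold (log2 change 3.06, SE 0.33, adjusted p = 0.0257), in Slc7a11, which this list shares with the ATF4 list, and in Gclc, the catalytic subunit of the rate-limiting enzyme of glutathione synthesis, at 4.06-fold (adjusted p = 0.0489). Txnrd1, Gclm and Gstp1 also rose. FBS replicate 3 lay above replicates 1 and 2 by a median of 0.37 on this list, and 18 members rose when it was left out. With an estimated correlation the adjusted p was 0.182, and with fry 0.00529.

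**Figure D2:**
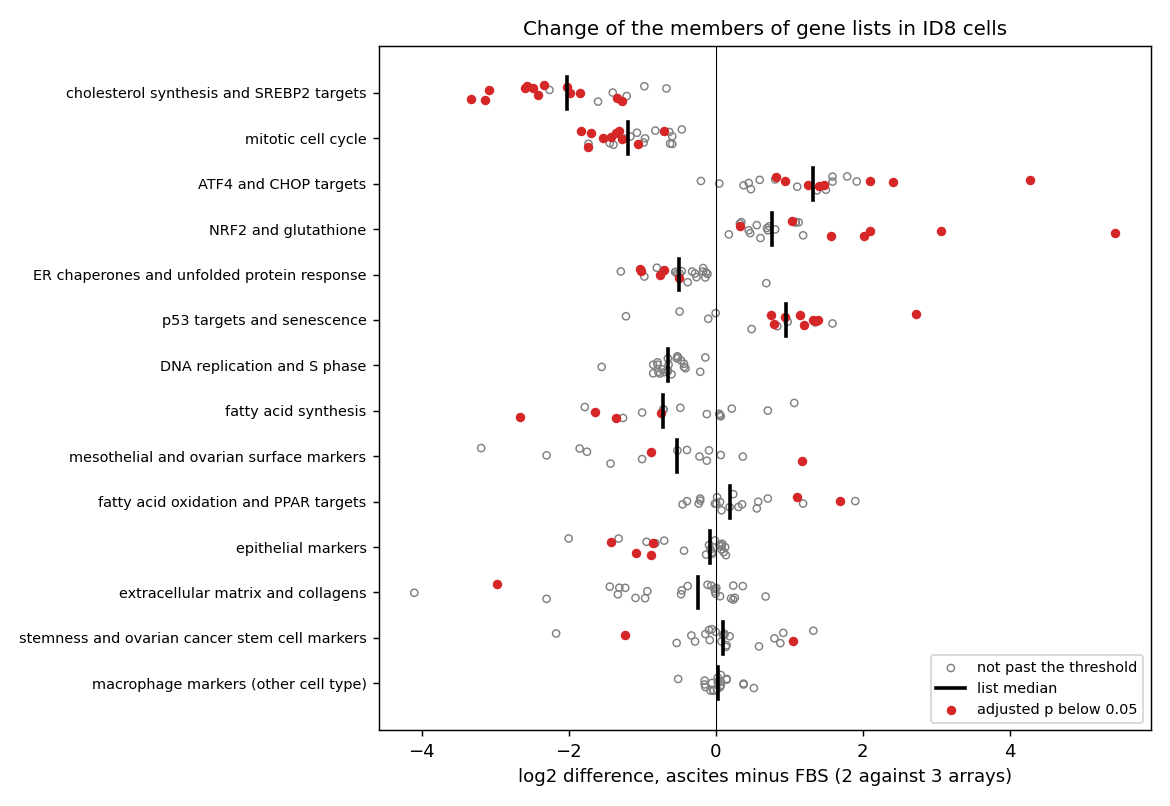
Log2 change, ascites minus FBS (2 against 3 arrays), of each measured member of 14 gene lists; every point is a gene, filled red where its adjusted p was below 0.05, and the black bar is the list median. The cholesterol list has the lowest median (-2.02) and the ATF4 list the highest (1.32), while stemness and macrophage markers centre near 0 (0.10 and 0.03).

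Hspa5 transcript did not differ detectably between the groups. Its signal was 13.99 ± 0.30 (SD, n = 3) in FBS and 13.85 ± 0.16 (SD, n = 2) in ascites. The log2 change was -0.14 (SE 0.20, 95% confidence interval -0.69 to 0.41, or 0.621-fold to 1.33-fold), with an adjusted p = 0.729. The exact two-sided permutation p was 0.6, where 0.1 is the smallest that 3 against 2 arrays allow. Without FBS replicate 3, whose Hspa5 signal was the lowest of the 5 arrays, the change was -0.31 (adjusted p = 0.129). The ER chaperone and unfolded protein response list, to which Hspa5 belongs, fell (camera adjusted p = 8.4e-08, median -0.49), with 23 of 24 members lower, 5 fallen over all genes, and 10 fallen and 1 risen adjusted over the list alone. The glycoprotein gene Creld2 was 2.04-fold lower, the disulfide isomerase gene Pdia6 2.03-fold, Manf 1.70-fold and Hsp90b1, which encodes GRP94, 1.62-fold (12.64 ± 0.05 against 11.94 ± 0.06, adjusted p = 0.0191). FBS replicate 3 lay below replicates 1 and 2 by a median of -0.19 on this list, and without it 15 members fell and 1 rose. The call was lost with an estimated correlation (adjusted p = 0.449) and kept with fry (0.0185).

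The list of stemness and ovarian cancer stem cell markers did not shift (camera adjusted p = 0.418, median 0.10 over 23 measured members). Fry gave an adjusted p of 0.0615, upward, and 3.36e-05 when members may move either way, a test that many other lists also passed. Many members were dim, with only 12 left once the lowest 25% of genes were left out (camera adjusted p = 0.196). Klf4, a pluripotency factor also active in differentiated epithelia, rose 2.07-fold (11.59 ± 0.16 to 12.64 ± 0.01, adjusted p = 0.0245). Lin28a fell from 5.81 ± 0.12 to 4.58 ± 0.37 (adjusted p = 0.0438), the latter not shown to lie above background, but its other probe set moved by 0.02, and its adjusted p was 0.0519 without FBS replicate 3. Adjusted over the list alone, 3 members rose and 1 fell. The remaining members did not pass over all genes, among them Myc (log2 change 1.33, SE 0.23, adjusted p = 0.0563), Kit (0.92, SE 0.24), Cd24a (0.88), Cd44 (0.80, SE 0.39) and Aldh1a1 (0.59, SE 0.30). Without FBS replicate 3, Cd44 (1.16, adjusted p = 0.00871) and Myc (1.48, adjusted p = 0.0309) passed upward beside Klf4, and Lgr5 (-1.33, adjusted p = 0.0441) passed downward, while the list did not shift (camera adjusted p = 0.498). Pou5f1, Sox2 and Prom1 were at low signal (4.38, 3.27 and 4.21 in FBS), with changes of 0.14, -0.05 and 0.19. Lgr5 changed by -2.17 (SE 0.92), with FBS replicate 3 at 9.14 against 6.68 and 6.58 in the other FBS arrays. Its ascites mean (5.3) was not shown to lie above background, so its changes are not exact.

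**Figure D3:**
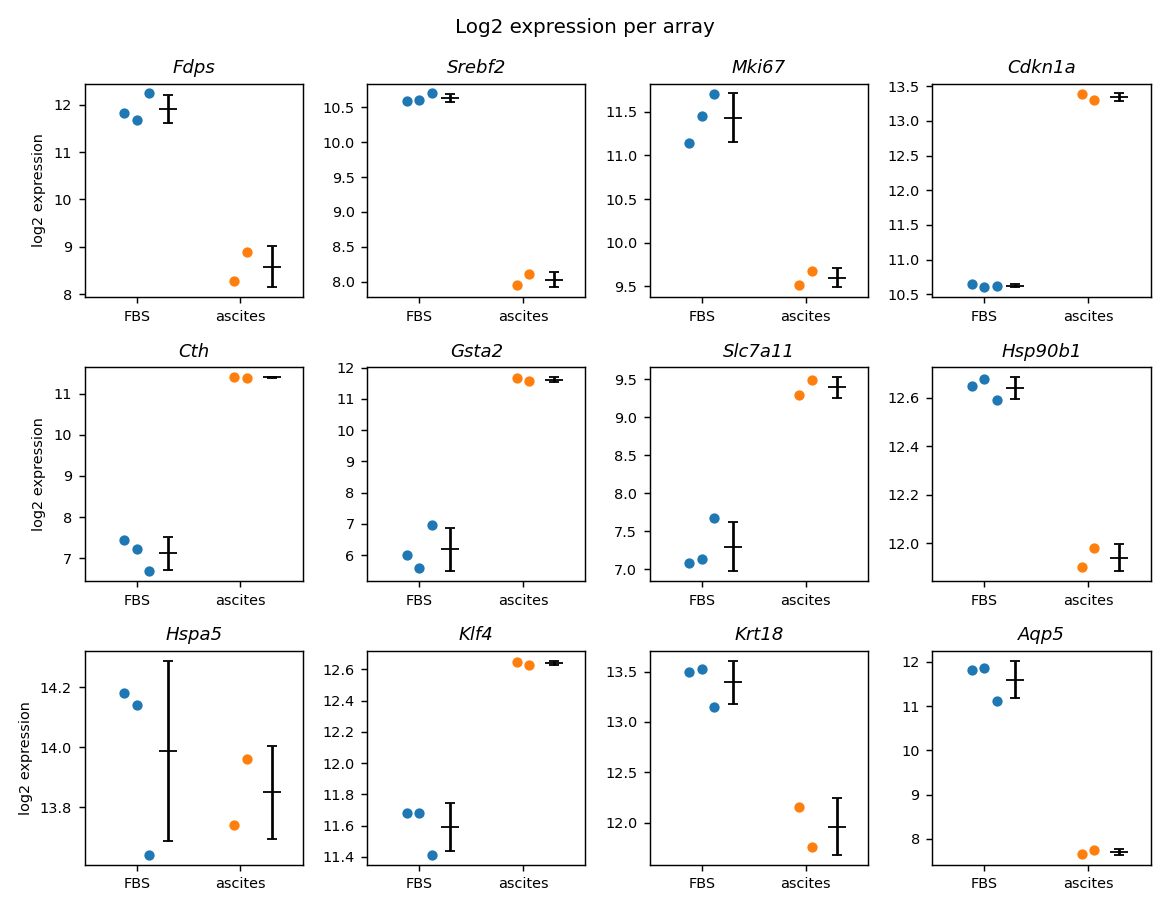
Log2 expression of 12 genes on each of the 5 arrays, blue for FBS and orange for ascites, with the group mean and SD as bars; the vertical axes differ between panels and do not start at 0. Cdkn1a lies near 10.62 in FBS and 13.34 in ascites with no overlap, while for Hspa5 the ascites arrays (13.74 and 13.96) lie within the range of the FBS arrays (13.64 to 14.18).

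Epithelial markers shifted down by camera (adjusted p = 0.0389), with 4 of 24 members fallen and 6 adjusted over the list alone. Keratin 18 (Krt18) was 2.70-fold lower (adjusted p = 0.0361), the tight junction gene Cldn3 2.13-fold, keratin 19 (Krt19) 1.84-fold and the splicing factor gene Esrp2 1.80-fold (another probe set moved by -0.19), while the list median was -0.08 and the adhesion gene Cdh1 changed by 0.05. Mesothelial and ovarian surface markers shifted down (camera adjusted p = 0.0332, median -0.52 over 15 members). In this list Krt19 fell and Nr2f2, a nuclear receptor gene, rose 2.26-fold (adjusted p = 0.0393), with 4 fallen and 1 risen adjusted over the list alone. Bnc1 (-3.19, SE 0.58), Upk3b (-2.30, SE 0.74) and Wt1 (-1.43, SE 0.34) did not pass over all genes. Extracellular matrix and collagen genes shifted down (camera adjusted p = 0.0389, median -0.25), with Mgp the 1 of 26 members that fell, and 4 fallen adjusted over the list alone. Col6a1 had the lowest change of the list, -4.10 (SE 0.76, adjusted p = 0.0624). FBS replicate 3 lay below replicates 1 and 2 by medians of -0.83 for mesothelial markers and -0.35 for matrix genes, and level with them for epithelial markers (0.00). Without it the mesothelial median was -0.89, with 9 members fallen and 1 risen, among the fallen Bnc1, Upk3b and Wt1, and 9 members fell in each of the epithelial and matrix lists. These 3 calls were lost without each of FBS replicates 1 and 2 and ascites replicates 2 and 3, when FBS replicates 1 and 2 were averaged (adjusted p = 0.0631, 0.0631 and 0.0829 in the order given), and with an estimated correlation (adjusted p = 0.449, 0.592 and 0.597). Fry kept the epithelial call (0.0243) and lost the mesothelial (0.195) and matrix (0.149) calls. The mesothelial call was also lost with the lowest 25% of genes left out. The matrix call was also lost with the replicate block (camera adjusted p = 0.123), with the lower 50% left out and with the mean of probe sets.

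Mesenchymal transition markers did not shift as a list (camera adjusted p = 0.0688, but 0.048 with an intensity trend in eBayes) and moved both ways. Snai2, the repressor Slug, rose 3.04-fold (adjusted p = 0.0158), S100a4 was 3.93-fold lower (adjusted p = 0.0177) and Vim (vimentin) 1.44-fold lower (adjusted p = 0.0463), and 20 of 23 members did not pass. Adjusted over the list alone, 3 rose and 5 fell. Hypoxia and glycolysis genes did not shift either (camera adjusted p = 0.191). Of their 22 members, the angiogenic factor gene Vegfa rose 3.68-fold (adjusted p = 0.0177), and Egln3 and Aldoc were 6.89-fold and 4.80-fold lower (adjusted p = 0.0204 and 0.0164), with the same counts of 1 risen and 2 fallen adjusted over the list alone. Another probe set of Aldoc moved by -0.44. Among 15 drug efflux transporters, 3 rose and 1 fell, and 3 rose and 4 fell adjusted over the list alone. Abca1, a cholesterol exporter, rose 6.61-fold (adjusted p = 0.0349), though another of its probe sets moved by 0.00. The multidrug transporter genes Abcb1b and Abcb1a rose from 3.54 ± 0.25 to 5.22 ± 0.14 and from 4.14 ± 0.14 to 5.24 ± 0.06, signals not shown to lie above background in either group, and Abca3 was 1.77-fold lower, with another probe set at 0.02. The median of that list was -0.05, its mean 0.23 and the camera direction down (adjusted p = 0.937), so these differ in sign. Without FBS replicate 3, the risen and fallen members were 2 and 5 for mesenchymal markers, 5 and 5 for hypoxia and 4 and 2 for transporters.

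The remaining signalling and immune lists did not pass by camera. The list of apoptosis regulators did pass, downward, without ascites replicate 3 (adjusted p = 0.0238), with median centring (0.0489) and with the lower 50% of genes left out (0.0495), and the STAT3 list in the last of these (0.0201). In the list of prosurvival and apoptosis regulators (adjusted p = 0.0665), Birc5, Casp8 and Mcl1 fell, the latter pair by 0.70 and by 0.68 on the log2 scale. Bmp2 and Smad6 fell 4.35-fold and 3.08-fold in the BMP list (adjusted p = 0.279), and Tgfb3 and Thbs1 fell 4.16-fold and 3.24-fold in the TGF-beta and YAP list (0.65). In the Wnt list (0.279) the cyclin D1 gene Ccnd1 rose 2.26-fold, Fzd2 fell 2.01-fold, and Rnf43 fell from 5.66 ± 0.23 to 4.26 ± 0.12, the latter not shown to lie above background. Notch2 fell 1.44-fold in the Notch and Hedgehog list (0.782). The STAT3 and acute phase list (0.354) held Saa3, which rose 3.95-fold, and Cp and Socs3, which fell 2.32-fold and 2.20-fold. In the interferon list (0.86) Oas1a rose 1.49-fold and Irf1 fell 2.03-fold, and in the NF-kB list (0.791) Vcam1 and Cx3cl1 rose 1.56-fold and 1.48-fold. Tapbp, a peptide-loading chaperone gene, fell 2.65-fold in the antigen presentation list (0.287). Blvrb, a biliverdin reductase gene, rose 3.52-fold and Cp fell in the iron and heme list (0.662). Adjusted over the list alone, the counts of risen and fallen members were 1 and 5 of 16 for apoptosis regulators, 1 and 3 of 16 for BMP, 2 and 2 of 21 for TGF-beta and YAP, and 2 and 4 of 23 for Wnt. They were 0 and 0 of 21 for Notch and Hedgehog, 1 and 2 of 20 for STAT3, 1 and 1 of 25 for interferon, 4 and 1 of 29 for NF-kB, 0 and 1 of 16 for antigen presentation, and 4 and 3 of 17 for iron and heme. By fry, apoptosis regulators and BMP targets moved down (adjusted p = 0.0107 and 0.00764) and the NF-kB list up (0.000838). The NF-kB and interferon lists had means of -0.04 and -0.03 against medians of 0.01 and 0.03 and an upward camera direction, so these differ in sign. In 5 of the genes named here another probe set moved little or the other way: Notch2 by 0.15, Cp by 0.16, Cx3cl1 by 0.04, Vcam1 by 0.18 and Mcl1 by -0.09. When FBS replicate 3 was left out, 2 members rose and 7 fell in the STAT3 list (camera adjusted p = 0.0942), and 3 rose and 6 fell among apoptosis regulators (0.0979). The risen and fallen members were then 1 and 5 for BMP, 2 and 3 for TGF-beta and YAP, 2 and 6 for Wnt, 0 and 4 for Notch and Hedgehog, 1 and 4 for interferon, 5 and 2 for NF-kB, 1 and 1 for antigen presentation, and 4 and 2 for iron and heme.

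Markers of other cell types that ascites fluid could carry showed no shift past the threshold. The lists of macrophage (20 measured members, camera adjusted p = 0.937), lymphocyte (16, 0.598), neutrophil (10, 0.881), erythroid (7, 0.868), endothelial (12, 0.287) and fibroblast markers (12, 0.937) had 0 members past the threshold, with 0 also adjusted over each list alone. Their medians lay between -0.02 and 0.04. Fry gave adjusted p values of 0.0615 (endothelial) and 0.0618 (lymphocyte), both upward, and 0.759 to 0.96 for the other lists. When members may move either way, fry passed the lymphocyte (0.000689), macrophage (0.00486), endothelial (0.0055) and fibroblast (0.0191) lists, as it did many other lists. The members with the smallest p were C1qc (-0.15), Cd2 (0.28), S100a9 (-0.17), Hbb-b2 (-0.13), Egfl7 (0.36) and Gsn (-0.78, SE 0.18, adjusted p = 0.0875). At an unadjusted p below 0.05 there were 11 of the 77 members, where 24.3% of all genes had such a p. Without FBS replicate 3, 6 members passed at the adjusted threshold. These were Cd2 (0.26) among lymphocyte markers, Esam (-1.16) among endothelial markers, and Pi16 (0.31), Pdgfra (-1.02), Dcn (-1.46) and Gsn (-0.94) among fibroblast markers, 4 of the 6 lower in ascites. The camera adjusted p of these lists then lay between 0.644 and 0.992.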

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

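A signal was present in data that the comparison of named genes did not use. Of 2246 probe sets without a single assigned gene in the annotation, 63 changed between ascites and FBS at an adjusted p below 0.05, 38 upward and 25 downward, and 19 of these 63 are assigned to several genes. Adjustment was over all probe sets of the array, of which 980 passed. These probe sets are given as counts, with no explanation tested.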

How the results depend on the processing

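Averaging FBS replicates 1 and 2 was chosen after the data were seen; the other settings were planned. The number of changed genes, 654 in the main comparison, did not hold. It was 2612 with array weights, which gave FBS replicate 3 a weight of 0.186 against 2.96 and 3.53 for FBS replicates 1 and 2, and 0 to 2494 when an array was left out, highest without FBS replicate 3 (644 of the 654 shared) and 0 when any other was left out. It was 0 with FBS replicates 1 and 2 averaged, 3 with the statistic without moderation, 208 against a 1.2-fold change and 6 at an adjusted p below 0.01. The other settings gave 478 (intensity trend) to 916 genes (median centring), within 1.5 times. All 654 kept their direction with quantile normalization, median centring and the mean of probe sets; where arrays were left out, averaged or blocked, the direction was fixed beforehand, since the groups did not overlap for these genes. Fewer arrays also mean fewer residual degrees of freedom. Leaving out or down-weighting FBS replicate 3 leaves the FBS spread mainly to the nearly alike replicates 1 and 2. The cause of each change was not tested further.

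With the replicate block, 0 genes passed in limma (1892 at an unadjusted p below 0.05), with 1 residual degree of freedom. Of 32 lists, 11 were called, and the matrix list was lost. The cholesterol list still had a camera adjusted p of 5.08e-15 in this setting, so such small values do not reflect agreement between arrays. Deviations from the group means correlated across genes at 0.03 for replicate 2 and 0.043 for replicate 3. The deviations of the ascites arrays mirror each other, and those of the FBS arrays are set mainly by replicate 3, so these values are nearly a single measure. They do not show whether arrays of the same number were paired.

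Of 32 lists, 12 were called with the preset correlation and 0 with an estimated correlation. Leaving out an array gave 7 to 11 lists, lowest without ascites replicate 2, and fry called 11. Lists not called in the main comparison but called in a setting with the preset correlation were apoptosis regulators, the STAT3 list and mesenchymal markers, all downward. Cholesterol, mitotic, ATF4, NRF2, ER chaperone, p53 and DNA replication lists were called in all 14 settings with the preset correlation. Hspa5 stayed short of the threshold in every setting, with changes of -0.31 to -0.03. Of the 80 named genes past the threshold, 79 passed without FBS replicate 3 and 0 when any other array was left out. The deposited values hold no detection call, so signal over background could not be set as a limit.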

Other observations

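The 8 lists added here, those of LXR targets and early-response genes included, the test of ascites exposure in FBS replicate 3, the test of the cholesterol list against FBS replicates 1 and 2, and the count of splits were chosen after the main results were seen. The predictions for the LXR and early-response lists were set before their medians were computed, and the remaining tests before their results. Abca1 had already been seen, but it was not the only such member. In all, 5 of 15 LXR targets and 2 of 21 early-response genes were already held in other lists or among the largest changes. The members outside these had medians of 0.05 (10 LXR targets) and -0.53 (19 early-response genes).

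Aminoacyl tRNA synthetase genes, which charge tRNAs for translation and include known ATF4 targets, were higher in ascites. Of 16 measured members 9 rose, led by Wars (log2 change 1.66, SE 0.12, adjusted p = 0.0177), Rars (1.45, SE 0.11, adjusted p = 0.0184) and Lars (1.22), with a median of 0.78 (camera adjusted p = 1.94e-07, and adjusted p = 0.218 with an estimated correlation). Qars, Hars and Kars changed by -0.40, -0.14 and -0.07. The list of serine, one-carbon and transsulfuration enzymes had 5 of 13 members risen (median 0.60), but 5 of the 13, Cth, Mthfd2, Phgdh, Psat1 and Shmt2, are also in the ATF4 list and had been seen, so no list test is given. Of the remaining 8 members 3 rose (median 0.33), the neutral amino acid transporter genes Slc1a4 (3.99-fold, SE 0.07, adjusted p = 0.00784) and Slc1a5 (log2 change 1.08) and the serine synthesis gene Psph (2.30-fold). Without FBS replicate 3, 12 synthetase genes rose and 1 fell, and 10 genes of the serine list rose.

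Among xenobiotic receptor targets, 5 of 17 members rose and 1 fell (median 0.11), but the list was written after Gsta2, Cyp3a13 and Abcb1a had been seen to rise, so no list test is given. Of the 12 members outside the other lists and the largest changes, 2 rose and 1 fell (median 0.01). The carboxylesterase gene Ces2g rose 4.27-fold and the aldehyde dehydrogenase gene Aldh3a1 2.69-fold, while Cyp1b1 was 3.14-fold lower and Cyp1a1 changed by -0.03. Of 17 lysosome and TFEB targets, Mitf (log2 change 2.20) and Sqstm1 (2.82-fold, SE 0.06, adjusted p = 0.0107) rose and Tfeb fell by 0.91 on the log2 scale (camera adjusted p = 0.0444, 0.218 with an estimated correlation). Ribosomal protein genes were shifted up slightly, with a median of 0.10 and 1 of 21 past the threshold (camera adjusted p = 0.00129, 0.218 with an estimated correlation). Retinoic acid targets were not shifted (median 0.03 over 9 members, camera adjusted p = 0.645). Leaving out FBS replicate 3 gave 7 risen and 2 fallen xenobiotic targets, 6 and 2 lysosome genes, 4 and 0 ribosomal protein genes and 0 and 1 retinoic acid targets. As in the rest of the comparison, 0 genes passed when FBS replicate 1 or 2 or ascites replicate 2 or 3 was left out.

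FBS replicate 3 stood apart from FBS replicates 1 and 2, with 428 genes at least 2-fold from their mean, 297 lower (Fxyd3 by 27.6-fold) and 131 higher (Mmp13 by 8.54-fold). RNA degradation or labelling as the whole cause was argued against by the 3' minus 5' control differences, which exceeded the range of the other arrays by at most 0.18, although that array was highest for both controls (Gapdh 0.22 against -0.05 to 0.04, beta-actin 0.34 against 0.24 to 0.31), so a lesser part stays open. A large share of macrophages, neutrophils or erythroid cells was argued against by their marker lists, whose highest median was 0.14. Lyz2, S100a8 and Hba-a1, abundant in such cells, were at 5.50, 4.94 and 5.71 in replicate 3. The lymphocyte and endothelial lists differed by medians of 0 and -0.04, which is weaker evidence, since their median levels were low (5.18 and 5.06). Fibroblasts stay open: their list differed by a median of 0.03, but its member Gsn was bright on every array (12.45 to 13.49). A small share of any of these cells stays open. So does a different make-up of the ID8 culture itself, its mesothelial list being lower by a median of -0.83. Ascites exposure as the whole cause was argued against by the cholesterol list, which was higher in that array by a median of 0.53, in 19 of 19 members, while ascites lowered it, though of the genes lower in replicate 3, 175 of 297 were also at least 2-fold lower in ascites than in FBS replicates 1 and 2 and 5 were higher (100 simulations with no effects gave 1.22 lower in both on average, independent lists 12.4), and of those higher, 40 of 131 were higher in ascites and 10 lower (independent lists 3.5). None of these values allows for genes set high in FBS replicates 1 and 2, which are nearly alike and serve as reference on both sides, so the overlap does not show whether replicate 3 or that pair is the unusual one, and culture density or passage was not tested.

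The cholesterol list had the lowest median of the 32 lists, though not the smallest adjusted p by fry or with an estimated correlation. Normalization or an intensity trend was argued against, since 0 of 10000 random lists matched on mean level had a median as low (their range was -0.47 to 0.42 against -2.02), and FBS replicate 3 alone was argued against by a median of -1.88 against FBS replicates 1 and 2. A candidate explanation is sterol loading of the cells by lipoproteins in ascites, under which LXR targets should rise. Abca1 and Pltp did rise, but the LXR targets other than Abca1 had a median of 0.02 over 14 members (interquartile range -0.54 to 0.10), and the whole list of 15 had 2 risen and 2 fallen (2 and 4 without FBS replicate 3), a median of 0.03 and a downward camera direction (adjusted p = 0.8). Some of these members, such as Scd2 and Srebf1, are also SREBP targets, so the test leaves sterol loading open.

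Mitotic genes were lower while p53 targets were higher. Normalization or an intensity trend was argued against, since 0 of 10000 matched lists had a median as low as the mitotic list's (range -0.44 to 0.45 against -1.19), and FBS replicate 3 alone by a median of -1.05 without it. Less growth factor signalling in ascites than in FBS may contribute: the early-response list, set as the test, had a median of -0.53 (15 of 21 members lower, interquartile range -1.29 to 0.03, camera adjusted p = 0.0273, and adjusted p = 0.218 with an estimated correlation). By limma 0 of its members passed over all genes (12 at an unadjusted p below 0.05, 5 adjusted over the list alone), without FBS replicate 3 its members went both ways, with 3 risen and 5 fallen, and Fosl1 (2.61) and Myc (1.33) lay in the other direction, so it stays a hypothesis. Stress of another kind, culture density and time in culture were not tested.

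The 5 arrays can be split into 2 and 3 in 10 ways, and 1 split, the real one, gave 654 genes. The highest other split, FBS replicates 1 and 2 against the rest, gave 312. With 10 splits the share cannot go below 0.1.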
